A study of Mus musculus with 6 samples.

How the data were processed

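Total RNA from the visual cortex of Mecp2 knockout mice and wild-type littermates aged 8 to 10 weeks was measured by RNA sequencing, with 3 libraries per genotype. Per the labels' protocols, ribosomal RNA was removed, the libraries kept strand with the dUTP method, fragments were 200 to 700 bp, and single reads of 49 bp were made. ERCC spike-in RNA had been added but was not used here. Samples were grouped by their titles, and each table column carries the title of a single sample. The labels call the samples separate replicates but do not state that each came from its own animal, so p-values measure only the spread between these samples, which may be technical.

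The values are a signal that the authors deposited as 1 exon read density per gene and library, in a table of 14168 genes with the Entrez identifier, symbol and length of each gene. Per the submitters' processing notes, reads were aligned with BWA 0.6.2 to the mouse genome build mm9. The gene annotation, the counting tool and its use of strand, the density's scale and any filter are not given in the sources used here. Values of overlapping or antisense genes are therefore uncertain. The columns follow nearly the same distribution, since 98.0% of ranks have the same value in all 6 columns to a relative tolerance of 1e-06, as quantile normalisation leaves them. Column totals therefore lie between 44853.4 and 44854.1 and say nothing of the sequencing depth, which is unknown. No read counts can be recovered, so no counting interval is given, and a value of 0 means only that a gene is listed at 0. Genes listed at 0 number 2559, 2597 and 2537 in knockout replicates 1 to 3, 2371, 2479 and 2464 in wild-type replicates 1 to 3, and 1836 in all 6. Every knockout library thus has more of them than any wild-type library. Whether this reflects detection or expression was not tested, so falls of genes with low density are less certain. Forcing columns to a shared distribution removes any change of total RNA per cell, and it fixes the values of the highest ranks. Actb, for example, has the same density, 154.8, in all 6 libraries.

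Genes were matched by Entrez identifier to a RefSeq table of assembly GRCm38.p6, which gave 14150 matches and was used for current symbols and, as an alternative, for gene spans. Exonic length and GC content came from the GENCODE vM21 annotation for 14083 genes. These builds differ from mm9, so no coordinates are given. The deposited length, used as gene length throughout, lay within 1% of the RefSeq span for 53.7% of genes and within 10% for 78.8%. For 16 genes the symbol had been turned into a date and was restored through the Entrez identifier.

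Genes with a mean density of at least 0.0449, which is 1 ppm of the median column total, were kept, leaving 10404. Densities were transformed to log2(density + 0.0224), a pseudocount of 0.5 ppm of that total, so fold changes of low genes are understated. Genotypes were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, genotype as the only term), and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The values were used as the authors scaled them. Because the deposited values were not counts, the form of test planned for densities was used.

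From 32 gene lists fixed before the data were examined, the 30 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The same lists were tested with a correlation estimated per list and with fry. Genes over 100 kb were tested against the others in the same way. The share of such genes among called genes was tested with a 2-sided Fisher's exact test. The shift of long genes in each library was compared between genotypes with a 2-sided exact permutation test, for which 3 against 3 libraries allow no p below 0.1. The genes named were set by a rule fixed beforehand, beginning with Mecp2. The rule then takes the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap, the 5 longest called genes, and the 2 to 4 members with the smallest p of each list described. Genes whose deposited symbol marks a predicted model or a small RNA fall outside the rule. Other genes named were chosen after their values were seen.

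The procedure was tested on 20 simulated data sets with 200 changed genes each and a median of 10359 genes tested. It recovered 74.0% of genes changed by 0.5 on the log2 scale, 93.1% of those changed by 1 and 99.3% of those changed by 1.5, and 6.65% of calls were false. A simulated shift of 0.05 in long genes was recovered as 0.050. The noise was drawn independently for each gene and library, without correlation between genes or length bias of single libraries. The simulation therefore does not measure how far such features affect the real calls or the real shift.

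Alternatives set beforehand were pseudocounts of 0.1 and 2 ppm, no filter and a filter at 5 ppm, other scalings, limma without the trend, with a robust trend and with array weights, a threshold of 0.1, length limits of 60 and 200 kb, leaving out each library, and the replicate number as a block. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.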

Results

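The visual cortex of mice lacking Mecp2 was compared with that of wild-type littermates. Mecp2 encodes a protein that binds methylated DNA, and mutations of the gene cause Rett syndrome. Total RNA was sequenced in 3 knockout and 3 wild-type libraries, and exon read density was available for 14168 genes, 10404 of which were tested. The densities had been brought to a shared distribution before deposit, so that column totals of 44853.4 to 44854.1 do not reflect depth. The comparison asked which genes change without Mecp2, and whether the change depends on the length of the gene.

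Mecp2 (Entrez 17257) itself fell in all 3 knockout libraries, from a density of 5.41 ± 0.285 in wild type to 0.485 ± 0.032 in the knockout (SD, n = 3 each). Knockout libraries stood at 0.449, 0.511 and 0.496, and wild-type libraries at 5.12, 5.44 and 5.68. The log2 fold change was −3.42 (SE 0.085, limma adjusted p = 1.6e-08). The remaining density was 8.96% of the wild-type value. The allele named in the labels is known as a partial deletion, and the table holds no value per exon, so the remaining density was not assigned to exons.

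Beyond Mecp2, the genes that rose most in the knockout cortex were Cabp7 and Irak1. Cabp7, which encodes a calcium-binding protein, rose from a density of 1.13 ± 0.176 to 2.35 ± 0.207 (SD, n = 3 each), a log2 fold change of 1.05 (SE 0.12, limma adjusted p = 0.0075). Irak1, a kinase of interleukin-1 receptor signalling whose gene lies close to Mecp2 on the X chromosome, rose from 2.28 ± 0.183 to 4.56 ± 0.304, by 0.99 (SE 0.082, limma adjusted p = 0.0012). Several of the next genes belong to myelinating glia. They were Aspa, the enzyme that splits N-acetylaspartate (0.76, SE 0.096), the gap junction gene Gjb1 (0.63, SE 0.11) and Tmem10, now named Opalin (0.61, SE 0.11). Other genes called higher were the BMP-binding factor Bmper (0.71, SE 0.098), the GDNF receptor Gfra1 (0.66, SE 0.12), the latrophilin Lphn2 (0.65, SE 0.081) and the secreted protein Nell1 (0.65, SE 0.075). The remaining genes of this group were BC022623 (0.77, SE 0.11), Ldlrad3 (0.62, SE 0.11) and the synaptic vesicle gene Vamp1 (0.61, SE 0.072).

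The falls were led by AW551984, from a density of 0.26 ± 0.036 to 0.0628 ± 0.018, with a log2 fold change of −1.74 (SE 0.22, limma adjusted p = 0.0083). Its knockout density lies near the filter of 0.0449. Glra3, a glycine receptor subunit, changed by −1.18 (SE 0.14), the T-type calcium channel gene Cacna1g by −0.81 (SE 0.074, limma adjusted p = 0.0018) and Accn4, an acid-sensing channel now named Asic4, by −0.79 (SE 0.12). Next were the neurotrophin Ntf3 at −1.01 (SE 0.16), the Wnt pathway ligand Rspo1 at −0.83 (SE 0.14), gastrin-releasing peptide (Grp) at −0.78 (SE 0.14) and the substance P precursor Tac1 at −0.75 (SE 0.11). The others were Tnnc1, a troponin subunit (−1.26, SE 0.19), the desmosomal gene Pkp2 (−1.003, SE 0.15), neuroglobin (Ngb, −0.74, SE 0.11) and Apba2bp, now named Necab3 (−0.71, SE 0.09). Outside the naming rule, and chosen after their values were seen, 3 called genes carry predicted-model symbols. They were 1190003J15Rik, now named Urah (−1.01, SE 0.18), A930008G19Rik, now named Fam53b (0.50, SE 0.086), and 2310005P05Rik, now named Eepd1 (0.50, SE 0.091).

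In all, limma called 59 genes, of which 33 were higher and 26 lower in the knockout, Mecp2 included. In each of the 59 the 3 knockout libraries lay wholly above or below the 3 wild-type libraries, a separation shown by 17.8% of tested genes where chance gives 10%. Changes were small, with a median absolute log2 fold change of 0.59 among called genes, and 8 exceeded 1 (1 higher, 7 lower). At an unadjusted p below 0.05 there were 1299 genes, 640 higher and 659 lower, against 520.2 expected by chance on average. Splits of the libraries that ignore genotype gave from 165 to 1080 such genes. They mix the genotypes on both sides, so real genotype changes add to their spread, and their counts do not measure chance alone. The count depended on single libraries, since limma called 82 genes (47 lower) without knockout replicate 1, 27 without knockout replicate 2, 19 without knockout replicate 3, and 18, 14 and 9 without wild-type replicates 1, 2 and 3. It was 28 with no filter, 9 without the intensity trend and 364 with array weights, and Mecp2, Irak1, Cacna1g and Nell1 passed in every setting run.

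**Figure D1:**
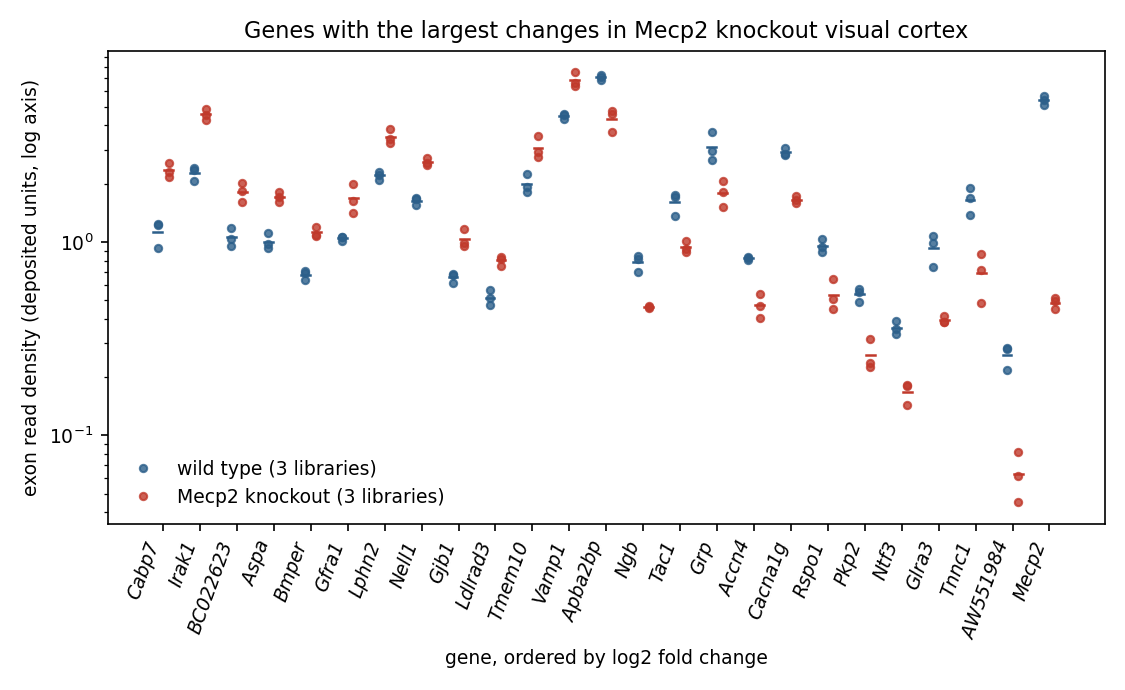
Exon read density in deposited units (log axis) of the called genes with the largest changes, ordered by log2 fold change, with 1 point per library (blue wild type, red Mecp2 knockout, 3 each) and a bar at the group mean. The genes other than Mecp2 were chosen to have no overlap between genotypes. Mecp2 has no overlap either and shows the widest gap, at mean densities of 5.41 and 0.485.

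Of 22 genes of myelinating oligodendrocytes tested, 6 were called higher, none lower and 16 did not pass. The median log2 fold change was 0.33, with 21 members positive. Besides Aspa, Gjb1 and Tmem10, the called genes were Ugt8a, an enzyme of myelin galactolipid synthesis (0.43, SE 0.064), the main myelin protein gene Plp1 (0.30, SE 0.05, from a density of 65.2 ± 0.799 to 80.5 ± 3.74) and Cnp1 (0.33, SE 0.061). Adjusted over the list alone, 18 were higher and 0 lower. The list passed camera (adjusted p = 8.4e-19), and stood at adjusted p = 0.105 with an estimated correlation. Its mean deviation from the 6-library mean was 0.17 ± 0.057 in knockout and −0.17 ± 0.0041 in wild-type libraries on the log2 scale (SD, n = 3 each).

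Of 19 genes tested in the neuropeptide list, Tac1 and Grp were called lower and no member was called higher. The median was −0.39, with 14 members negative and 5 positive. With p adjusted over the list alone, 10 were lower and 1, Crhbp, which encodes a binding protein of corticotropin-releasing hormone, was higher. Cartpt stood at −0.89 (SE 0.18) and Vip at −0.39 (SE 0.081), neither passing over all genes. The list passed camera (adjusted p = 1.4e-06), with adjusted p = 0.357 with an estimated correlation.

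Long genes of cell adhesion and synapse organisation had a median of 0.15 over 35 tested members, 32 of which exceed 100 kb. The ephrin receptor gene Epha7 was called higher (0.52, SE 0.07). There were 11 higher and 2 lower when adjusted over the list alone. Sdk1 stood at 0.68 (SE 0.14), Pcdh17 at 0.36 (SE 0.077) and Cntn6 at −0.35 (SE 0.077), none passing over all genes. The list passed camera (adjusted p = 1.0e-05), with adjusted p = 0.629 with an estimated correlation.

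Markers of meninges and fibroblasts had a median of −0.36 over 16 genes, 15 of them negative, and none was called by limma, over all genes or adjusted over the list alone, while 7 had an unadjusted p below 0.05. Igf2 stood at −0.45 (SE 0.14), Col1a2 at −0.52 (SE 0.17) and Bgn at −0.37 (SE 0.14). The list passed camera (adjusted p = 8.3e-05), with adjusted p = 0.629 with an estimated correlation. Knockout replicate 2 stood apart, at −0.54 from the 6-library mean, against 0.078 and −0.021 in the other knockout libraries. Without it the mean change was −0.13 and camera's adjusted p was 0.146.

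Immediate-early genes, which neuronal activity induces, had a median of 0.18 over 31 tested genes, and Ier5 was called higher (0.48, SE 0.059). Members higher when adjusted over the list alone numbered 3, the others being Nr4a2 (0.67, SE 0.16) and Fosl2 (0.42, SE 0.099), and none was lower. The list passed camera (adjusted p = 0.0078), with adjusted p = 0.775 with an estimated correlation. Knockout replicate 2 again stood apart, at 0.47, while knockout replicate 1 stood at −0.25. Without knockout replicate 2 the mean change was −0.011 (camera adjusted p = 0.706), and without wild-type replicate 3 it was 0.12 (camera adjusted p = 0.069).

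No member was called by limma in the last 3 lists that passed camera, where 7, 3 and 5 members had an unadjusted p below 0.05. Imprinted genes had a median of 0.11 over 17 genes (camera adjusted p = 0.0098, and adjusted p = 0.381 with an estimated correlation). Their knockout replicate 3 lay at −0.00052 from the 6-library mean, within the wild-type range of −0.075 to 0.0057. Knockout replicates 1 and 2 lay at 0.10 and 0.035. Adjusted over the list alone, Plagl1 (0.46, SE 0.094), Sgce (0.37, SE 0.1) and Peg3 (0.27, SE 0.073) were higher and Igf2 lower. Markers of choroid plexus and ependyma had a median of 0.19 over 5 genes (camera adjusted p = 0.035, and adjusted p = 0.405 with an estimated correlation), with Prlr higher adjusted over the list alone (0.86, SE 0.24). Enpp2 (0.15, SE 0.059) is also in the oligodendrocyte list, and Ttr stood at −0.28 (SE 0.49). Knockout replicate 2 lay at −0.11 from the 6-library mean, within the wild-type range of −0.22 to −0.091, against 0.38 and 0.16 in knockout replicates 1 and 3. That list did not pass with no filter (camera adjusted p = 0.528), nor without knockout replicate 1 (0.168) or wild-type replicate 3 (0.0706). Glucocorticoid-induced genes had a median of −0.051 and a mean of −0.16 over 19 genes (camera adjusted p = 0.036, and adjusted p = 0.697 with an estimated correlation). Adjusted over the list alone, Map3k6 (−0.54, SE 0.13), Sult1a1 (−0.41, SE 0.1), Fkbp5 (−0.31, SE 0.097) and S3-12, now named Plin4, (−0.73, SE 0.23) were lower. Knockout replicate 3 lay at 0.082, within the wild-type range of 0.012 to 0.14, against −0.25 and −0.075 in knockout replicates 1 and 2, and the mean change was −0.076 without knockout replicate 1. That list did not pass without the intensity trend (0.0572), with array weights (0.378), or without knockout replicate 1 (0.771) or wild-type replicate 2 (0.163).

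Of the 30 lists, 8 passed camera with the preset correlation, 0 with an estimated correlation (where 3 had an unadjusted p below 0.05), and 2 passed fry, those of oligodendrocytes (adjusted p = 0.022) and imprinted genes (adjusted p = 0.045). Splits of the libraries that ignore genotype passed up to 14 lists by camera with the preset correlation, though they mix the genotypes and do not measure chance alone.

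**Figure D2:**
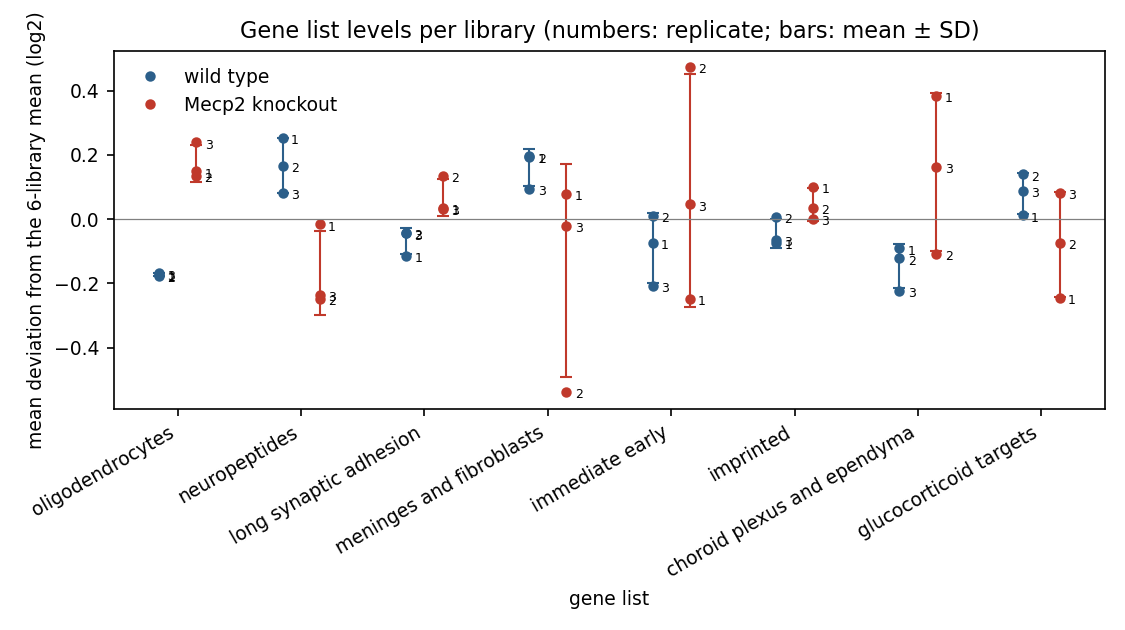
Mean deviation of each gene list from the 6-library mean (log2 scale) in wild-type (blue) and Mecp2 knockout (red) libraries, for the 8 lists that passed camera with the preset correlation. Points are libraries with their replicate number and bars are mean ± SD (n = 3); oligodendrocyte genes lie at 0.17 ± 0.057 in knockout against −0.17 ± 0.0041 in wild type, and knockout replicate 2 lies apart in meningeal and immediate-early genes.

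Among neurons, single markers changed while the lists did not pass camera in the main comparison. Of 24 markers of GABAergic interneurons, Pvalb, the calcium-binding protein of fast-spiking cells, rose by 0.47 (SE 0.068, from a density of 7.38 ± 0.424 to 10.2 ± 0.719), and Tac1 fell. There were 2 higher and 6 lower adjusted over the list alone, with Syt2 at 0.48 (SE 0.094) and Vip at −0.39. The median was 0.027, while camera's direction was down (adjusted p = 0.942). Of 26 markers of glutamatergic neurons and layers, Rspo1 fell, and adjusted over the list alone 4 were higher and 2 lower, with Slc17a6 at 0.55 (SE 0.1). Their median was 0.038 (camera adjusted p = 0.591). Pan-neuronal markers had a median of 0.051 over 17 genes with 0 called by limma and 2 at an unadjusted p below 0.05 (camera adjusted p = 0.0777), Elavl4 standing at 0.19 (SE 0.056) and Syn2 at 0.13 (SE 0.052). Their mean of 0.067 moved with single libraries. The list passed camera without knockout replicate 1 (mean 0.097, adjusted p = 0.026), knockout replicate 3 (0.084, adjusted p = 0.033) or wild-type replicate 2 (0.094, adjusted p = 0.025), and the mean was 0.021 without knockout replicate 2 (adjusted p = 0.551) and 0.038 without wild-type replicate 1 (adjusted p = 0.321).

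Of 36 voltage-gated channel genes, 2 were called lower, Cacna1g and the sodium channel subunit gene Scn3b (−0.58, SE 0.053, limma adjusted p = 0.0018), and none higher. The counts adjusted over the list alone were 4 higher, among them Scn4b (0.49, SE 0.1), and 4 lower, among them Cacnb3 (−0.31, SE 0.06). The median was 0.011, while the mean was −0.016 and camera's direction was down (adjusted p = 0.847). Of 16 glutamate receptor subunits, Grik4, of the kainate receptor, rose by 0.46 (SE 0.084), alone also when adjusted over the list alone. Grid1 stood at 0.19 (SE 0.061). The median of −0.038 and the mean of −0.0034 differed in sign from camera's direction, up (adjusted p = 0.999).

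The lists of other cell types did not pass camera with all 6 libraries. Medians were −0.045 over 22 astrocyte markers (camera adjusted p = 0.847), where the mean was 0.0098, 0.055 over 21 microglial markers (0.999), where the mean was −0.0062, and 0.0020 over 22 endothelial and mural markers (0.884). Markers of oligodendrocyte precursors had a median of −0.12 over 15 genes (camera adjusted p = 0.153), and passed without knockout replicate 1 (mean −0.17, adjusted p = 0.026) or wild-type replicate 3 (−0.16, adjusted p = 0.040). None of these lists had a called member, while at an unadjusted limma p below 0.05 they had 1, 3, 3 and 8, in the same order. Of the precursor markers 2 were higher and 6 lower adjusted over the list alone, with Sox10 at 0.36 (SE 0.083) and C1ql1 at −0.63 (SE 0.17). Kcnj8, a mural marker, was higher by the same measure (0.66, SE 0.13), and no other endothelial, mural, astrocyte or microglial marker was higher or lower by it.

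Long genes had slightly higher log2 fold changes than others. The median was 0.037 over the 1318 tested genes over 100 kb and −0.0049 over the other 9086, a difference of 0.042, or 2.97%. Of the long genes 62.1% had a positive value, against 48.6% of the others. The median went from −0.015 in genes up to 10 kb, through −0.012, 0.00061, 0.014 and 0.031 in those up to 25, 50, 100 and 250 kb, to 0.056 in the 312 genes over 250 kb. Across genes, which are not independent replicates, Spearman's rho between length and log2 fold change was 0.116 and Pearson's r was 0.108. The set of long genes passed camera (p = 1.24e-04), but not with an estimated correlation, 0.0513, at which p = 0.155, nor fry for change in a shared direction (p = 0.1, against p = 0.0014 for change in either direction). The difference of medians was 0.028 without knockout replicate 2 and 0.025 without wild-type replicate 1, and rho was 0.0372 and 0.0371. Given expression, exonic length and GC content the partial rank correlation was 0.0512.

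The shift of long genes varied between libraries of the same genotype. As the mean over long genes minus that over the others, knockout replicates 1 to 3 stood at 0.0077, 0.07 and 0.023 and wild-type replicates at −0.066, −0.021 and −0.014 on the log2 scale. The means were 0.034 ± 0.032 and −0.034 ± 0.028 (SD, n = 3 each), a difference of 0.067 with an exact permutation p = 0.1, the smallest that 3 against 3 libraries allow. The 3 knockout values lay above the 3 wild-type values.

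Among called genes, long ones were concentrated on the higher side. Of the 33 higher genes 15 exceeded 100 kb (45.5%, against 12.7% of tested genes), with an odds ratio of 5.80 (Fisher's exact p = 3.57e-06, adjusted over both directions p = 7.14e-06). Fisher's test takes genes as independent, while long genes had an estimated correlation of 0.0513, so its p-values may be too small. Of the 26 lower genes 1, Glra3, was that long (3.85%, Fisher's exact p = 0.243). This deficit passed without knockout replicate 1 (−10.6 percentage points, Fisher's exact p = 0.0255) and with array weights (−5.11, Fisher's exact p = 0.0483), and was an excess of 3.99 points without wild-type replicate 3 (Fisher's exact p = 0.557). The 5 longest called genes all rose, Nell1 (887940 bp, 0.65), Sema5a, an axon guidance gene (451529 bp, 0.54, SE 0.096), Grik4 (423938 bp, 0.46), the protein kinase C gene Prkca (405681 bp, 0.37, SE 0.059) and Bmper (262127 bp, 0.71). The excess of long genes among higher genes did not pass without knockout replicate 3 (Fisher's exact p = 0.0697) or wild-type replicates 1, 2 or 3 (0.22, 0.27 and 0.334), where fewer genes were called.

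**Figure D3:**
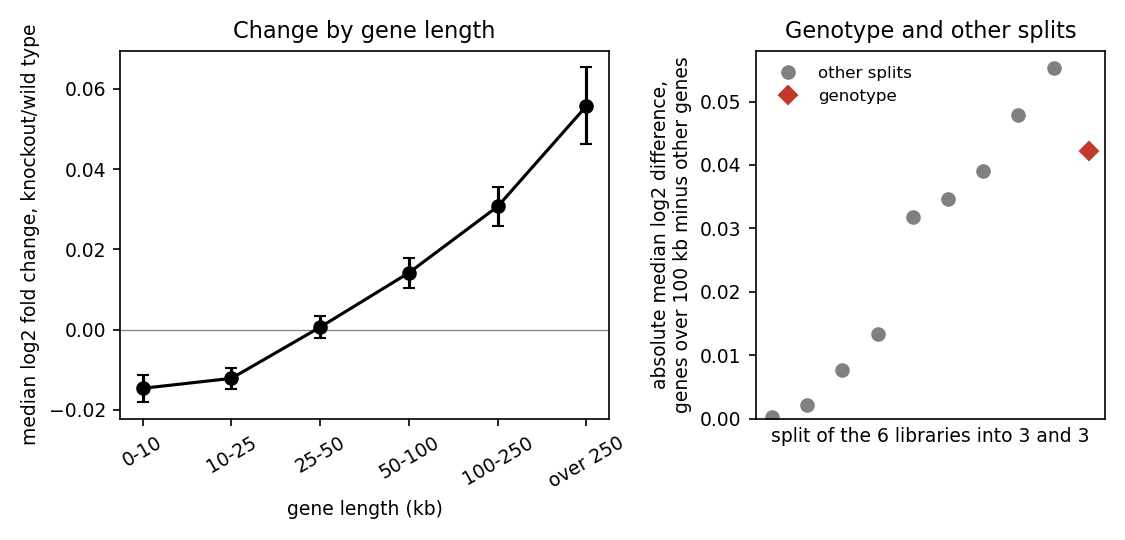
Left, median log2 fold change (knockout over wild type) of tested genes by gene length in kb, with bars for the bootstrap standard error over genes, from −0.015 up to 10 kb to 0.056 over 250 kb. Right, absolute difference of medians between genes over 100 kb and the others for the 10 splits of the 6 libraries into 3 and 3, in rising order with the genotype split last (red diamond, 0.042); 2 other splits (grey) lie above it, the highest at 0.0553.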

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

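Thresholds, lists and settings were chosen before the data were examined, except gene spans from RefSeq and, for the length shift per library, leaving out libraries and the block, which were added afterwards. The fall of Mecp2 kept its call in all 17 settings (−3.46 to −3.37 without single libraries). Counts of called genes moved most. In total, higher and lower, limma called 28, 15 and 13 with no filter, 9, 4 and 5 without the trend, 364, 192 and 172 with array weights, and 227, 118 and 109 at a threshold of 0.1. Leaving out each library gave 9 to 82 in total, 3 to 35 higher and 6 to 47 lower. The cause was not tested. The replicate number as a block gave 440 calls (230 higher, 210 lower), the 59 among them, and ended the call of the choroid plexus list (camera adjusted p = 0.0504), but of no other list or named gene that passed. Clock genes (0.0081) and pan-neuronal markers (0.022) passed only then and without single libraries. The labels do not say that a shared number marks a shared litter or batch. Same-numbered libraries deviated together with correlations of 0.317, 0.187 and 0.0756, not all above 0.1, the limit used here for treating them as pairs. Each knockout library correlated best with its own number, a hint of pairing from the data and not the design, so pairing is not excluded. Long genes kept a higher median in all settings (0.025 to 0.062 without single libraries), but their set did not pass with an estimated correlation (0.042, p = 0.155), nor did any gene list (0), against 8 to 10 lists without single libraries. The rank correlation with length lay between 0.0371 and 0.169 without single libraries, and was 0.0727 with array weights and 0.14 with exonic length. The share of long genes among higher genes exceeded that of tested genes by 12.3 to 27.3 percentage points without single libraries. Among lower genes it passed as a deficit with array weights (−5.11 points, Fisher's exact p = 0.0483), with the block (−6.48, p = 0.0031) and without knockout replicate 1 (−10.6, p = 0.0255), ranged from −12.7 to 3.99 without single libraries, and was an excess, 3.99, without wild-type replicate 3. The cause was not tested. Immediate-early genes turned to −0.011 without knockout replicate 2, in a range of −0.011 to 0.35 without single libraries. Of the 27 genes named for size or length, 21 did not pass without the trend, 12 with no filter and 1 with a pseudocount of 2 ppm. Of 162 combinations of gene and library left out, 86 did not pass. No sign could change there, because the genotypes did not overlap in any of these genes. Tests for counts were not run, because the values are not counts, and no symbol had duplicate rows. Rescaling moved little because the columns already share a distribution. The unknown depth leaves the precision of low genes unknown.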

Other observations

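Other fixed lists held single called genes without passing as lists. Of 25 genes named in earlier work as regulated or bound by MeCP2, some of them picked on other Mecp2 mutant brains, Irak1 was called higher and Tac1 lower by limma. There were 2 higher adjusted over the list alone, with Sdk1 at 0.68, and 5 lower, with Sst at −0.28. Their median was −0.034 (camera adjusted p = 0.658). Of 23 genes near Mecp2 on the X chromosome, Irak1 alone was called, also when adjusted over the list alone. At an unadjusted limma p below 0.05 there were 7, Irak1 among them, and of all 23 there were 15 negative and 8 positive. The median was −0.020 and the mean 0.024 (camera adjusted p = 0.942), with Bcap31 at −0.18 (SE 0.064). DNA methylation enzymes and corepressor genes had a median of 0.013 over 19 members, none called by limma and 0 at an unadjusted p below 0.05 (camera adjusted p = 0.769). Hdac2 stood at −0.13 (SE 0.063).

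Markers of regions next to the visual cortex went in both directions. Of 14 hippocampal genes Grp was called lower. Adjusted over the list alone, 5 were lower, with Nov, now named Ccn3, at −0.43 (SE 0.082), and 1 higher, Man1a, at 0.36 (SE 0.1). Their median was 0.073, while the mean was −0.024 and camera's direction was down (adjusted p = 0.531). Of 13 striatal and thalamic genes Tac1 was called lower. Of the 13, 4 were higher adjusted over the list alone, with Slc17a6 at 0.55 and Ppp1r1b at 0.28 (SE 0.059), and 3 lower, with Penk1 at −0.41 (SE 0.088). Their median was 0.17 (camera adjusted p = 0.660). No member was called in the other lists, which did not pass camera in the main comparison. Medians were −0.090 for GABA receptor subunits (adjusted p = 0.0743), 0.083 for cholesterol synthesis (0.0957), 0.072 for clock genes (0.171), −0.056 for ribosomal proteins (0.171), 0.019 for oxidative phosphorylation (0.471), 0.074 for replication histones (0.780), 0.032 for blood (0.942) and −0.0097 for heat shock and unfolded protein genes (0.999). In the same order these lists had 1, 5, 1, 1, 1, 1, 0 and 4 genes at an unadjusted limma p below 0.05, and 1, Insig1 of cholesterol synthesis, was higher adjusted over the list alone (0.35, SE 0.082). Leaving out a single library made 5 of these lists pass camera. They were cholesterol synthesis without knockout replicate 1 (adjusted p = 0.013), clock genes without knockout replicate 1 (0.020) or wild-type replicate 2 (0.048), GABA receptor subunits without knockout replicate 2 (0.0050), oxidative phosphorylation without knockout replicate 2 (0.0050) or wild-type replicate 1 (0.0010), and ribosomal proteins without wild-type replicate 2 (0.032) or 3 (0.044).

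Tests chosen only after the results were seen were those of length bias between single libraries, of the oligodendrocyte rise, of knockout replicate 2 and of detection among long genes, and the splits for the length correlation, the number of lists and oligodendrocyte genes. Matching on density and exonic length was planned, but its use as a test of exonic length alone was set afterwards. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The genotype split called 59 genes and no other split called any, with 0 as the highest other count by limma, while 165 to 1080 genes had an unadjusted p below 0.05 in the other splits. The other splits mix the genotypes on both sides, so real genotype changes widen their spread and make calls less likely. In number of splits with a value as large, the real one included, the count of genes gave 1, the mean of oligodendrocyte genes 1 (0.35, highest other 0.15), the length correlation 5 (0.116, highest other 0.236) and the number of lists 8 (8, highest other 14). The 3 other splits with most genes at an unadjusted p below 0.05 (856, 902 and 1080) all put knockout replicate 1 and wild-type replicate 1 together, whose deviations correlated at 0.317, but a further split that does so had 327. Whether these libraries share a batch is not given by the labels.

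The small upward shift of long genes may not depend on genotype. The difference of 0.042 was 1.48 times the spread of 0.0286 expected for 3-library means from differences between libraries of the same genotype. Of 6 such pairs of single libraries 4 differed by more, but single libraries vary more than means of 3. With the genotype split included, 3 of the 10 splits gave as much (highest other 0.0553), so length bias of single libraries remains a candidate cause. The measures differ, since by means per library the shift was 0.067 against a pooled SD of 0.030 within genotype. On that measure no other split gave as much, at an exact permutation p = 0.1, the smallest possible. Markers of all neurons had a median of 0.051 ± 0.022 (SE over genes), as a larger share of neuronal RNA would give. Their mean of 0.067 ranged from 0.021 without knockout replicate 2 to 0.097 without knockout replicate 1, so that this stays open. Against other genes matched on density and exonic length the shift was 0.035 ± 0.0058 (SE over genes), above 50% of its value, 0.0211. With the trends in exonic length and GC content removed it was 0.020 ± 0.0045 (SE over genes), too close to 0.0211 to decide. These standard errors leave out the spread of 0.0286 between libraries. Exonic length alone, these biases jointly and genotype therefore cannot be told apart. Better detection of small changes was argued against for the long genes among called ones. Of other genes matched on density and exonic length 0.228% were called higher, 3 genes, against 1.14% of long genes (Fisher's exact p = 0.0073). That p takes genes as independent, so it may be too small.

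The higher level of the oligodendrocyte list extended to its most abundant transcripts, Plp1, and Mbp at densities of 47.2 in knockout and 37.5 in wild type (0.33, SE 0.099, not called). A lower share of neurons would raise every other cell type alike. The highest median among astrocyte, microglial, endothelial and precursor markers was 0.055, in microglia, 2.69 standard errors below that of oligodendrocytes. Those standard errors are over genes and leave out correlation between markers. By library, mean deviations in knockout and wild type were 0.0049 ± 0.045 and −0.0049 ± 0.085 for astrocytes (SD, n = 3 each). Microglial markers stood at −0.0031 ± 0.082 and 0.0031 ± 0.14, endothelial at 0.016 ± 0.093 and −0.016 ± 0.025, and precursors at −0.051 ± 0.12 and 0.051 ± 0.14. None differed beyond its spread, and pan-neuronal markers did not fall, with a median of 0.051 and 15 of 17 positive. Both argue against a lower share of neurons, though the pan-neuronal list did not pass camera in the main comparison. With 3 libraries per genotype, small differences could be missed. More oligodendrocytes or more white matter in the knockout samples remains open, as 95.5% of the listed markers were positive, from −0.0037 to 0.76, and higher transcription per cell would look alike here. Visual cortex contains these cells, no sort removed them, and 1 of the 22 markers, Enpp2, also stands in the choroid plexus list.

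Knockout replicate 2 alone may account for the shifts in immediate-early and in meningeal genes. Without it the mean change of immediate-early genes went from 0.18 to −0.011, and that of meningeal and fibroblast genes from −0.32 to −0.13, and neither list passed camera (adjusted p = 0.706 and 0.146). Ier5, Nr4a2 and Fosl2, the immediate-early genes higher adjusted over the list alone, did not overlap between genotypes. Their rise was thus not confined to that library. They were picked by small p, however, and 17.8% of all tested genes did not overlap, so they do not speak for the list. The most abundant members were Arc, at densities of 35.8 in knockout and 26.0 in wild type, and Ptgds, at 101.1 and 113.8. Among immediate-early genes 4 of 31, and among meningeal genes 1 of 16, also stand in another list. A difference of neuronal activity or of dissection in that sample is a candidate source for both, while an effect of genotype on either list was not shown to be absent.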
